A study of Drosophila melanogaster with 17 samples.

How the data were processed

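Total RNA from whole testes of adult fruit flies (Drosophila melanogaster) was labelled and hybridized to Affymetrix 3' expression arrays, 17 arrays in 10 groups. About 250 ng of total RNA per array was used, per the labels. The knockdown experiment comprised 10 arrays, 2 biological replicates in each of 5 groups, from flies 0 to 1 day old grown at 30 °C. The heat-shock experiment comprised 7 arrays from flies of the bam mutant genotype grown at 25 °C. Of these, 2 arrays carried no hs-Bam transgene (1 without heat shock and 1 taken 24 h after it). The other arrays carried hs-Bam, with 2 arrays without heat shock, 2 taken 24 h after it and 1 taken 48 h after it. The heat shock lasted 30 minutes at 37 °C.

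The deposited values of every table were log2 expression levels made with GCRMA, which adjusts the background and normalizes arrays to a common distribution. Per the file headers, this was done in R 3.0.2. The values came in 3 separately normalized sets, each with its own floor, the lowest value that a probe set can take. The floor was log2 2.095 in the table of the knockdown arrays, 2.186 in the 6 heat-shock arrays of the value table and 2.13 in the table that holds the 48 h array. The table with the 48 h array also held 4 hs-Bam arrays and 4 knockdown arrays in a second normalization. The knockdown arrays and the 48 h array had identical values in the value table and in their own tables. In the knockdown table and the 48 h table, 18 columns (12 and 6) belonged to other experiments and were not used, although their arrays took part in the authors' normalization. All comparisons were made within 1 set.

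Each table held 18952 probe sets, of which 14049 were listed in the probe annotation. A single gene symbol was given for 13647 of them, covering 11982 genes, and the 402 with several symbols and the 4903 unnamed here were left out of the gene tests. Probe sets were kept when their value was at least log2 4 on at least 2 arrays of the fit, and the probe set with the highest mean represented each gene. This left 9817 genes in the knockdown arrays, 6626 in the heat-shock arrays and 7097 in the 5 hs-Bam arrays of the 48 h table. Arrays have no read depth: their number, 2 per group or fewer, limits the precision. Between 50.0% and 55.4% of probe sets reached log2 4 on a knockdown array, against 41.4% to 42.1% on a heat-shock array.

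Linear models with 1 mean per group were fitted with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with default settings, without a replicate term. P values were adjusted over all genes tested with the Benjamini-Hochberg method, and a gene counted as changed at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Errors given with ± are moderated standard errors from limma, in log2 units. All tests were two-sided except Fisher's exact test of overlap, which was one-sided. The 48 h group held 1 array, so its spread was assumed to equal that of the other hs-Bam groups.

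Gene lists were fixed before the data were examined, as were the comparisons, thresholds, filter and the rule for named genes. They were spermatogonial and piRNA germline genes, DNA replication genes, tMAC complex genes, testis TAF genes, meiotic cell cycle genes, spermatid differentiation genes, cup and comet genes, Y-linked fertility genes, testis-specific proteasome genes, NuRD and dMec complex genes, homeobox and other Polycomb target genes, heat shock genes, antimicrobial peptide genes and cytoplasmic ribosomal protein genes. Markers of other cell types were neuronal, glial, photoreceptor, muscle, fat body, haemocyte, digestive enzyme, accessory gland and ejaculatory duct, oogenesis and testis somatic cell genes. Each list was tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. camera compares a list with the other genes, and fry tests whether its members moved one way on balance. None of the camera calls in any comparison held with an estimated correlation: the lowest adjusted p was 0.22.

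Named genes were kmg, Mi-2, aly, bam and Dcr-2, the 10 largest rises and falls among changed genes whose groups did not overlap, and up to 4 changed members of each list (or the 2 members with the smallest p where none changed). Genes named outside this rule are said to have been chosen after their values were seen. Genes raised by a knockdown were counted as raised from background where their own control mean was below log2 4. The fry tests of raised genes were adjusted together over 24 tests.

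The fits were tested on simulated data with the group means of the arrays, in 5 draws per comparison. Each draw changed 50 genes per size of change, with noise independent between genes and arrays and without a floor. The knockdown data had far larger shares of changed genes, and all arrays had values at the floor, so recovery and false calls may differ there. Gene variances were first set to limma's moderated variances and then, after those results were seen, drawn from limma's fitted prior, which gave lower recovery. The accepted minimum, 95% recovery in the kmg RNAi comparison, was first set for changes of log2 3, was missed there with the fitted prior (94.4%) and was then moved to log2 5 (99.2%). The values that follow are from the fitted prior, with those from moderated variances in parentheses. With 2 arrays against 2 in the knockdown set, 88.8% (95.2%) of simulated changes of log2 2 were recovered, with 7.8 (7.4) false calls per draw among 9817 genes. In the heat-shock set 39.6% (82.4%) were recovered at 24 h, and 91.6% (98.8%) at a change of log2 5. False calls there numbered 5.8 (11.8) per draw among 6626 genes. With the single 48 h array 2% (40.4%) were recovered at a change of log2 2 and 82.4% (96.4%) at a change of log2 5. Alternatives covered the filter, the normalization, the variance prior, all probe sets, the fold minimum, a replicate term, the arrays included in the fit and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.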

Results

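Transcript levels were measured on arrays from whole testes in 10 groups. The knockdown arrays addressed what is lost and gained when kmg (also CG5204, or kumgang) or Mi-2 (the chromatin remodeler dMi-2) is depleted in differentiating male germ cells. In the flies labelled RNAi, bam-gal4 drove the hairpin in late spermatogonia and early spermatocytes together with UAS-dicer2, and the control flies carried the balancer chromosome TM6b in place of the driver. A further group was labelled kmg RNAi with bam-gal4 and mutant alleles of aly, a gene of the tMAC complex that switches on spermatocyte and spermatid genes. The labels of that group gave no UAS-dicer2, and the series held no aly mutant without kmg RNAi. In the heat-shock arrays, bam mutant testes, which hold proliferating spermatogonia, were to receive a pulse of Bam. It was meant to make germ cells enter the spermatocyte program together. Median values per array ran from log2 4.01 to 5.22 in the knockdown set and from 2.23 to 2.24 in the heat-shock set. Replicates correlated across genes at 0.975 to 0.997 in the knockdown groups and at 0.946 to 0.957 in the hs-Bam groups, where genes are not independent replicates. Genes of the accessory gland, a seminal fluid organ that was to be dissected away per the labels, had a median of log2 11.65 in dMi-2 control replicate 1 and 10.3 in dMi-2 RNAi replicate 1. On the other knockdown arrays this median lay between 2.29 and 2.82.

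The kmg transcript fell in kmg RNAi testes, from a mean of log2 9.67 to 5.25, a change of -4.42 ± 0.14 (21.4-fold, adjusted p = 1.9e-07, n = 2 and 2). The arrays labelled kmg RNAi with aly mutant had kmg at 9.06, which was 3.81 ± 0.14 above kmg RNAi (adjusted p = 7.3e-08) and -0.61 ± 0.14 from kmg control, a difference below the fold minimum. The kmg level on these arrays was thus near that of kmg control, unlike in kmg RNAi. Most tMAC and testis TAF genes were higher there than in kmg control, so the kmg level alone does not tell whether the hairpin worked. Mi-2 fell in dMi-2 RNAi testes from 8.89 to 7.53 (-1.36 ± 0.25, adjusted p = 0.0011), while kmg rose there to 11.38 (1.66 ± 0.14, adjusted p = 1.4e-05). Mi-2 differed by -0.46 ± 0.25 in kmg RNAi and was not called (adjusted p = 0.14). The aly transcript was not called in either comparison of the arrays labelled aly mutant (-0.44 ± 0.2 against kmg RNAi, where the sign changed under a scaling alternative, and -0.64 ± 0.2 against kmg control), and it rose by 1.24 ± 0.2 in dMi-2 RNAi, a call lost without dMi-2 RNAi replicate 2. The bam transcript rose by 1.47 ± 0.26 in kmg RNAi and by 1.82 ± 0.26 in dMi-2 RNAi. Dcr-2 rose by 2.44 ± 0.22 in dMi-2 RNAi and was not called in kmg RNAi (0.78 ± 0.22).

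**Figure D1:**
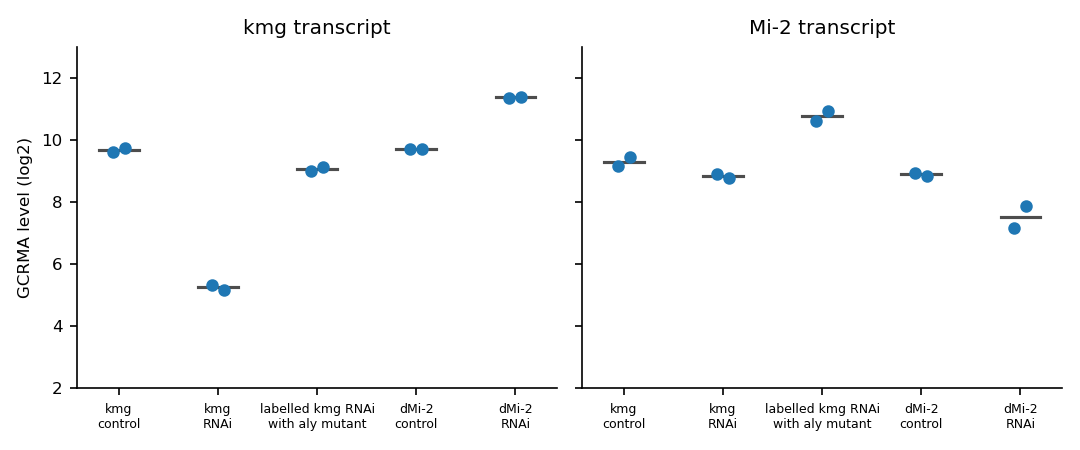
Levels (GCRMA, log2) of the kmg and Mi-2 transcripts on each knockdown array, with points for arrays and lines for group means, n = 2 per group. The kmg mean is 5.25 in kmg RNAi and 9.06 in the arrays labelled kmg RNAi with aly mutant, and the Mi-2 mean is 7.53 in dMi-2 RNAi.

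After kmg RNAi some genes of unrelated cell types were higher and a part of the late spermatogenic genes was lower. No list of other cell types passed camera. The largest rise was that of Osi22, an Osiris family gene, from log2 2.1, at the floor, to 12.46 (10.37 ± 0.17, adjusted p = 1.4e-08). Obp73a, an odorant-binding protein gene, rose by 9.59 ± 0.3 and Gyc89Db, a guanylyl cyclase subunit gene, by 9.06 ± 0.35. The other rises in the top 10 were those of CG11626, CG18493, CG7906, hll, CG31437, CG6296 and CG7695, between 8.33 and 9.06. The largest falls were those of CG4161 (-8.78 ± 0.13) and of klhl10 (-8.72 ± 0.22), a gene of a ubiquitin ligase that activates caspases in spermatids. CG31867, CG32457, CG42710, CG31296, CG31677, CG10588, CG33287 and CG33233 fell by 7.7 to 8.7. In all, 4679 of 9817 genes changed (47.7%), 2520 higher and 2159 lower. Higher genes outnumbered lower ones as deposited, but not after quantile normalization (2345 and 2442) or median centring (2337 and 2483), which moved the median of all genes from 0 to -0.06 and -0.14. Where a control mean lay at the floor, the fold change depends on the floor.

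Among markers of other cell types, 6 of 7 measured photoreceptor genes rose after kmg RNAi, among them inaD, a scaffold of the phototransduction complex (7.09 ± 0.51), inaC, a protein kinase C (6.4 ± 0.23), and trp, a light-activated channel (4.06 ± 0.34), while Arr1, an arrestin, fell by 5.94. Of 9 glial genes 5 rose and 1 fell. The glial determinants gcm2 (6.76 ± 0.48), repo (5.65 ± 0.28) and gcm (4.38 ± 0.26) were among those that rose. Of 10 homeobox and other Polycomb target genes 6 rose and 1 fell, with vg at 5.05 ± 0.27, ems at 4.86 ± 0.4, pb at 4.45 ± 0.33 and Dll at 4.37 ± 0.17. Of 11 oogenesis genes 7 rose and 0 fell, among them the eggshell gene dec (4.41 ± 0.27), the maternal determinant bcd (3.79 ± 0.23) and the eggshell genes Vm26Aa (3.66 ± 0.31) and Cp16 (3.51 ± 0.25). None of these 4 lists passed camera (adjusted p of 0.11, 0.14, 0.056 and 0.056). All 4 passed fry (limma fry adjusted p of 0.00073, 4.3e-06, 4.4e-06 and 4.4e-05), which tests against no change rather than against the other genes and called 16 of 24 lists under kmg RNAi. Their members called after adjustment over the list alone numbered 7, 6, 7 and 7. For repo, alrm, inaC, trp, Mal-A1, Vm26Aa, Cp16, CG7695 and NimC1 the filter was passed through both kmg RNAi arrays, and without either one these genes were not tested. The 4 lists held 16, 10, 20 and 17 genes before the filter. A gene below log2 4 on the control arrays was measured only if at least 2 other arrays reached it. The shares and fry p values of all marker lists in the comparisons of a knockdown with its control thus favour rises, as for the digestive list, with 4 of 13 genes measured. For genes that only the kmg RNAi arrays brought past the filter, a comparison against kmg RNAi could show only a fall.

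The remaining marker lists did not pass camera under kmg RNAi. Of 13 neuronal genes 5 rose, such as Gad1, a GABA synthesis gene (4.1 ± 0.46), and 2 fell, nSyb (-2.32 ± 0.35) and unc-13 (-2.31 ± 0.44). Of 16 muscle genes 4 rose and 6 fell, with Act88F, a flight muscle actin, at 3.47 ± 0.41 and sls at -3.89 ± 0.51, where the probe sets of sls disagreed. Of 9 haemocyte genes 4 rose, led by PPO1 (5.72 ± 0.53), of 4 digestive enzyme genes 3 rose and 1 fell, led by Mal-A1 (6.46 ± 0.47), and of 5 fat body genes 1 rose (Fbp2, 4.48 ± 0.79) and 1 fell (Tsf1, -2.93 ± 0.56). Of 6 testis somatic cell genes 2 rose and 2 fell, and of 16 accessory gland and ejaculatory duct genes 1 fell (Ebp, -2.78 ± 0.2). The errors of accessory gland genes were widened by the dMi-2 arrays that carried these transcripts. In a fit of the kmg RNAi and kmg control arrays alone, chosen after seeing the data as were the genes named from it, 3 of 6 measured genes were higher (Acp32CD, 4.87 ± 0.13, Acp29AB and Acp36DE) and 1 was lower. Mean and median differed in sign for the accessory gland, testis somatic cell, testis TAF and heat shock lists, camera pointed down for the fat body and tMAC lists against a positive median and mean, and the medians of the tMAC, testis TAF, haemocyte and heat shock lists, between -0.16 and 0.2, changed sign under a scaling alternative.

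Of the germline lists, those of Y-linked, cup and comet and DNA replication genes passed camera under kmg RNAi, and those of spermatogonial and spermatid genes did not. All 7 measured Y-linked fertility genes fell (camera adjusted p = 0.00089, adjusted p = 0.4 with an estimated correlation), with the axonemal dynein genes kl-3 at -6.14 ± 0.3 and kl-2 at -4.28 ± 0.19, Ppr-Y at -5.01 ± 0.16 and ORY at -3.73 ± 0.31. Of 13 cup and comet genes, which are transcribed in spermatids, 7 fell and 0 rose (camera adjusted p = 0.003, adjusted p = 0.42 with an estimated correlation), among them t-cup (-5.32 ± 0.21), d-cup (-4.11 ± 0.21), sunz (-3.95 ± 0.19) and schuy (-3.43 ± 0.17). Of 21 spermatid differentiation genes 4 fell, Mst36Fa (-3.56 ± 0.29), Prtl99C (-1.51 ± 0.19), ProtB (-1.33 ± 0.49) and dj (-1.02 ± 0.15), and the other 17 were not called (camera adjusted p = 0.11). ProtB was not called without either kmg control array or kmg RNAi replicate 1, and dj not without kmg control replicate 1. Of 9 testis-specific proteasome genes 3 fell, led by Prosalpha4T1 (-4.83 ± 0.19). Of 12 DNA replication genes 7 rose and 0 fell (camera adjusted p = 0.013, adjusted p = 0.4 with an estimated correlation), with the ribonucleotide reductase gene RnrL at 4.45 ± 0.21, Orc1 at 4.41 ± 0.18, PolA1 at 2.86 ± 0.22 and dup at 2.74 ± 0.21. Adjusted over the list alone, the same numbers of Y-linked, cup and comet and replication genes were called (7, 7 and 7), and 3 of the spermatid genes.

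Among the spermatocyte regulators, 0 of 9 tMAC complex genes were called under kmg RNAi. Of 5 testis TAF genes, Taf12L rose (1.26 ± 0.13) while can (-1.14 ± 0.19) and nht (-1.09 ± 0.15) fell, the call of nht being lost without kmg RNAi replicate 1. Of 10 meiotic cell cycle genes 3 rose, twe, the meiotic Cdc25 phosphatase (2.45 ± 0.33), tef (1.92 ± 0.2) and CycB (1.66 ± 0.24), and SA2 fell by 1.44. Of 15 spermatogonial and piRNA germline genes 4 rose, led by the RNA helicase gene vas (4.81 ± 0.21), and AGO3 fell by 1.97. Of 5 NuRD and dMec complex genes, which include partners of dMi-2, 1 rose (MTA1-like, 1.15 ± 0.41, not called without either kmg control array or without kmg RNAi replicate 2), and 0 of 5 heat shock genes and 0 of 2 antimicrobial peptide genes were called. Of 37 cytoplasmic ribosomal protein genes 4 rose and 3 fell, although the list passed camera upward (median 0.61, adjusted p = 0.013, adjusted p = 0.87 with an estimated correlation). The 3 that fell, RpS28-like (-3.61 ± 0.33), RpS28a (-3.06 ± 0.43) and RpL10Aa (-1.64 ± 0.22), are paralogs of other ribosomal protein genes.

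In dMi-2 RNAi many more genes were higher than in kmg RNAi, and spermatid genes were lower by more. The arrays read whole testes, and whether a changed mix of cells accounts for such differences was not tested for either knockdown. Genes called raised or lowered in the knockdowns are therefore those at higher or lower levels in the whole testis. Ac78C, an adenylyl cyclase gene, rose by 8.57 ± 0.24 (adjusted p = 2.1e-08), ndl, a protease gene of eggshell patterning, by 8.49 ± 0.28 and Osi22 by 8.37 ± 0.17. Cht7, chp, Lkr, 7B2, CG43366, Obp73a and dyl followed, with rises of 7.17 to 8.22. CG13725 fell by 10.85 (adjusted p = 4.5e-09), CG31204 by 10.73, the testis proteasome gene Prosbeta5R1 by 10.52 and t-cup by 10.4. CG30350, CG31816, Fpgs2, CG14391, Pif2 and CG11298 changed by -10.47 to -10.34. In all, 6568 genes changed (66.9%), 4446 higher and 2122 lower, and the median of all genes was 0.84 above control (0.61 after median centring). Without the replicate 1 arrays of both dMi-2 groups, which carried accessory gland transcripts, 6389 genes changed, of which 6113 were shared with the fit of all arrays.

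Of 21 spermatid differentiation genes 17 fell in dMi-2 RNAi and 0 rose (camera adjusted p = 1.1e-07, adjusted p = 0.49 with an estimated correlation), with the chromatin protein gene Prtl99C at -7.12 ± 0.19, fzo, a mitofusin of spermatid mitochondria, at -6.46 ± 0.22, Mst36Fa at -5.77 ± 0.29 and S-Lap5 at -3.93 ± 0.34. Of 13 cup and comet genes 12 fell (median -4.39, camera adjusted p = 1.5e-07, adjusted p = 0.26 with an estimated correlation), and all 7 Y-linked fertility genes fell (median -5.83, camera adjusted p = 1.6e-05, adjusted p = 0.26 with an estimated correlation), led by Pp1-Y2 at -8.43 ± 0.2. Of 9 testis-specific proteasome genes 7 fell and 1 rose (camera adjusted p = 0.0013, adjusted p = 0.36 with an estimated correlation), with Prosalpha3T at -8.93 ± 0.18 and Prosalpha4T1 at -8.74 ± 0.19. Of 37 ribosomal protein genes 30 rose and 3 fell (median 1.49, camera adjusted p = 0.0034, adjusted p = 0.79 with an estimated correlation), and the 3 that fell were again RpL10Aa (-8.49 ± 0.22), RpS28-like (-7.74 ± 0.33) and RpS28a (-6.71 ± 0.43). Adjusted over the list alone, 17, 12, 7, 8 and 33 members of these 5 lists were called.

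Of 15 spermatogonial and piRNA germline genes 10 rose in dMi-2 RNAi and 0 fell, with vas at 4.44 ± 0.21, qin at 3.09 ± 0.22, aub at 2.69 ± 0.23 and nanos at 2.47 ± 0.3. Of 12 DNA replication genes 6 rose, led by Orc1 (5.1 ± 0.18), and of 9 tMAC genes 3 rose, Caf1-55, wuc and aly. Among markers of other cell types, 5 of 7 photoreceptor genes rose, with the cell surface gene chp at 7.87 ± 0.37, and Arr1 fell by 5.59, and 5 of 9 glial genes rose, led by gcm (4.92 ± 0.26). Of 10 Polycomb target genes 7 rose, with vg at 5.51 ± 0.27 and ems at 4.58 ± 0.4, and 2 fell, with ftz at -6.07 ± 0.23. Of 16 muscle genes 13 rose and 2 fell, of 13 neuronal genes 6 rose and 2 fell, of 9 haemocyte genes 6 rose, and of 11 oogenesis genes 5 rose. Of 16 accessory gland genes 1 fell (Ebp, -3.54 ± 0.2), while replicate 1 lay above replicate 2 by a median of 9.05 in the controls and 6.67 in dMi-2 RNAi. Of 5 testis TAF genes 2 rose, of 10 meiotic genes 3 rose and 2 fell, and of 5 NuRD and dMec genes 3 rose (Caf1-55, HDAC1 and MTA1-like) and 1 fell, Mi-2 itself. The smaller lists gave 2 fat body genes higher and 2 lower of 5, 1 digestive enzyme gene higher and 1 lower of 4, 3 testis somatic genes higher and 1 lower of 6, 4 of 5 heat shock genes higher and 0 of 2 antimicrobial peptide genes called. None of the lists in this paragraph passed camera, while fry called 21 of 24 lists in dMi-2 RNAi. The medians of the fat body and digestive lists (0.28 and 0.18) differed in sign from their means (-0.17 and -0.54). These medians and that of the meiotic list (0.13), for which camera pointed down, changed sign under a scaling alternative.

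The knockdowns shared a large part of their changes. Both raised 1914 genes, against 1141.3 for independent lists (odds ratio 5.94, one-sided Fisher p = 5.2e-289, genes not being independent), and both lowered 1203, against 466.7 (odds ratio 9.22). Opposite changes were found for 62 genes (higher in kmg RNAi and lower in dMi-2 RNAi) and 310 genes (the reverse), against 544.7 and 977.8 for independent lists. The comparisons used separate control arrays, so that no array error entered both fold changes. Their calls rested on the same estimate of the spread per gene, however, which can favour calls in both. Both comparisons also set flies with bam-gal4 and UAS-dicer2 against flies with TM6b. Any effects of these would be common to both comparisons and were not separated from those of the hairpins. Across genes, the fold changes correlated at r = 0.621 (Spearman 0.605). Named genes raised by both included Osi22, Obp73a, gcm, gcm2, inaD, vg, ems, bcd, vas, Orc1 and RnrL. The genes raised by dMi-2 RNAi had a median change of 0.75 in kmg RNAi (limma fry adjusted p = 9.2e-06), with 1914 higher and 310 lower of 4446.

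**Figure D2:**
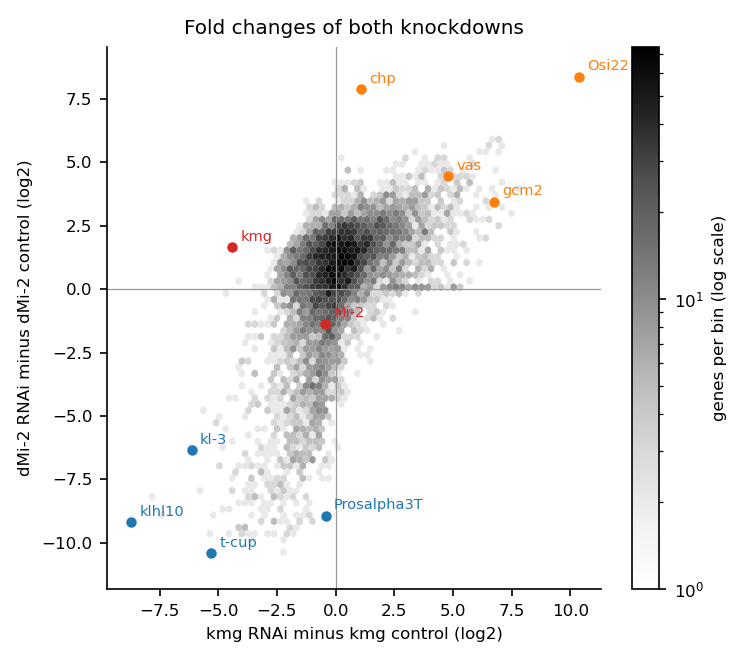
Log2 fold changes of 9817 genes in kmg RNAi (horizontal) and dMi-2 RNAi (vertical), with grey bins shaded by the number of genes and named genes as points. Across genes the fold changes correlate at r = 0.621, while Prosalpha3T falls in dMi-2 RNAi and chp rises there with smaller changes in kmg RNAi.

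The effects of both knockdowns differed for 5680 genes (57.9%), 2461 with the kmg effect above the dMi-2 effect and 3219 with it below. Most spermatid and proteasome genes were lowered less in kmg RNAi than in dMi-2 RNAi. Prosalpha3T differed by 8.5 ± 0.25 (adjusted p = 3.2e-07), fzo by 6.08 ± 0.31 and Prtl99C by 5.61 ± 0.26. Outside these lists, SmydA-2 differed by 8.67 ± 0.23 and the Y-linked gene Pp1-Y2 by 7.39 ± 0.28. Of 21 spermatid genes 16 had the higher value in kmg RNAi (median 1.39, camera adjusted p = 5.3e-05, adjusted p = 0.51 with an estimated correlation), as had 11 of 13 cup and comet genes (median 3.1, camera adjusted p = 5.9e-05, adjusted p = 0.51 with an estimated correlation) and 6 of 9 proteasome genes (camera adjusted p = 0.019, adjusted p = 0.51 with an estimated correlation). Of the proteasome genes 1 had the lower value in kmg RNAi. The glial gene repo (5.24 ± 0.39), the synaptic gene brp (5.46 ± 0.4), the photoreceptor gene inaC (5.27 ± 0.32) and the digestive gene Mal-A1 (6.23 ± 0.66) also had higher effects in kmg RNAi. As repo, inaC and Mal-A1 passed the filter only through both kmg RNAi arrays, the filter favoured this direction for them. The effect on chp was lower in kmg RNAi by 6.81 ± 0.53, that on CG3257 by 6.41 ± 0.37 and that on unc-13 by 5.22 ± 0.62. Of 15 spermatogonial genes 10 were lower in kmg RNAi, such as aub (-2.36 ± 0.32), and 14 ribosomal protein genes were lower and 3 higher (camera adjusted p = 0.013, adjusted p = 0.8 with an estimated correlation). Adjusted over the list alone, 16, 11, 7, 10 and 17 members of these lists were called. For the neuronal, glial and photoreceptor lists the medians (-0.83, -0.12 and -0.31) differed in sign from the means (0.03, 0.53 and 0.43). No other list passed camera, and fry called 14 of 24.

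The arrays labelled kmg RNAi with aly mutant were compared with kmg RNAi to ask which of the knockdown expression needs aly, a question that the kmg level of these arrays leaves confounded. Spermatid genes were lost. CG2127, the largest fall, went from log2 14.56 to 2.73 (-11.84 ± 0.21, adjusted p = 2.7e-09), followed by CG31948, CG12860, CG31870, CG30393, CG15208, CG5089, CG14448, CG4669 and CG31538 at -11.78 to -11.09. CG14635 (6.28 ± 0.42), CG13108 (6.13 ± 0.28) and the neuropeptide gene Dh31 (6.01 ± 0.32) rose most, ahead of OdsH, CG18823, ranshi, Tango6, CG9143, CG30096 and CG6254. In all, 7129 genes changed (72.6%), 4216 higher and 2913 lower, with a median of 0.64 over all genes (0.51 after median centring).

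Of 21 spermatid differentiation genes 20 fell (median -5.76, camera adjusted p = 2.9e-08, adjusted p = 0.41 with an estimated correlation), with the sperm tail gene dj at -10.42 ± 0.15, S-Lap5 at -9.09 ± 0.34, Prtl99C at -9.07 ± 0.19 and the sperm chromatin gene Mst77F at -8.48 ± 0.19. Of 13 cup and comet genes 11 fell (median -4.97, camera adjusted p = 0.00013, adjusted p = 0.41 with an estimated correlation), led by c-cup (-8.96 ± 0.48). Of 10 meiotic genes 5 fell and 2 rose, with CycB at -3.9 ± 0.24, twe at -3.84 ± 0.33 and bol at -4.54 ± 0.26, where the probe sets of bol disagreed. The testis TAF genes nht (3.85 ± 0.15), can (3.68 ± 0.19) and sa (2.08 ± 0.15) rose, as did 6 of 9 tMAC genes, led by comr (3.58 ± 0.23), and all 5 NuRD and dMec genes, led by HDAC1 (3.24 ± 0.37). Of 9 proteasome genes 6 fell and 3 rose, of 7 Y-linked genes 4 fell, of 15 spermatogonial genes 12 rose and 1 fell, of 12 replication genes 7 rose, and of 37 ribosomal protein genes 15 rose and 3 fell (camera adjusted p = 0.035, adjusted p = 0.67 with an estimated correlation). Adjusted over the list alone, 20 spermatid, 11 cup and comet and 18 ribosomal protein genes were called.

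Of 43 Polycomb target genes and markers of other cell types that kmg RNAi raised, 32 were lower in the arrays labelled aly mutant than in kmg RNAi, 2 were higher and 9 were not called, in comparisons that share the kmg RNAi arrays. All 7 raised oogenesis genes, 5 of 6 Polycomb target genes and 4 of 5 glial genes were lower, against 3 of 6 photoreceptor genes and 1 of 4 muscle genes. Against kmg RNAi, the photoreceptor genes inaD (-7.09 ± 0.51), inaC (-5.35 ± 0.23) and trp (-4.15 ± 0.34), the glial genes gcm2 (-7.08 ± 0.48) and repo (-5.65 ± 0.28), the eggshell gene dec (-7.15 ± 0.27) and the digestive gene Mal-A1 (-6.46 ± 0.47) fell. Of these, inaC, trp, repo and Mal-A1 passed the filter only through both kmg RNAi arrays, so that only a fall could be seen. The same holds for alrm, Vm26Aa and Cp16 in the list counts. Of 11 oogenesis genes 8 fell and 3 rose, of 10 Polycomb target genes 7 fell and 1 rose, such as pb (-4.46 ± 0.33), ap (-3.96 ± 0.25), Dll (-3.77 ± 0.17) and ftz (-3.76 ± 0.23), and all 4 digestive genes fell (camera adjusted p of 0.058, 0.062 and 0.058, with 20 of 24 lists called by fry). The photoreceptor gene chp rose instead (5.08 ± 0.37). Of the other lists, 4 glial genes rose and 4 fell of 9, 2 photoreceptor genes rose and 3 fell of 7, 7 neuronal genes rose and 3 fell of 13, 9 muscle genes rose and 2 fell of 16, 2 fat body genes rose and 2 fell of 5, 4 haemocyte genes rose and 3 fell of 9, 4 testis somatic genes rose and 2 fell of 6, 1 accessory gland gene rose and 1 fell of 16 (median 0.04 and mean -0.41, with the sign of the median changing under a scaling alternative, and 2 higher and 3 lower of 6 in a fit of these arrays alone), 4 of 5 heat shock genes rose and 1 of 2 antimicrobial peptide genes rose. Of the 2520 genes raised by kmg RNAi, 1210 fell and 407 rose, with a median of -0.89 (limma fry adjusted p = 6.6e-05), which was -0.65 and -0.57 without kmg RNAi replicate 1 and 2, respectively. As kmg RNAi arrays enter both comparisons, genes were also chosen on the first kmg RNAi array alone and compared with the second, which gave a median of -0.89 over 2545 genes, and -0.76 with the arrays exchanged. Both arrays had served in the filter, however, so genes that passed it only through them could only fall. Of the 937 genes raised from background 711 fell (75.9%) and 83 rose, with a median of -2.83. The genes raised by dMi-2 RNAi, chosen on other arrays, had a median of 1.27 (limma fry adjusted p = 1.5e-05), with 2505 higher and 800 lower, and the 1004 of them raised from background had a median of -0.99, with 497 lower and 290 higher.

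**Figure D3:**
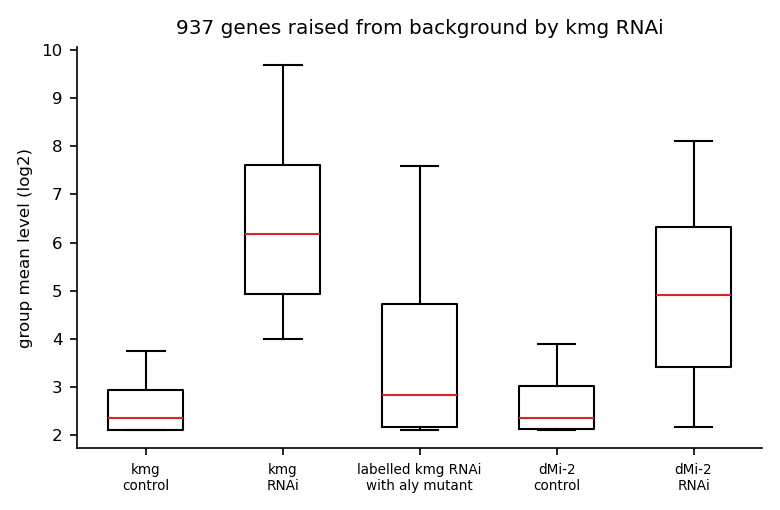
Group mean levels (log2) of the 937 genes that kmg RNAi raised from background, as boxes for the quartiles, red lines for the medians and whiskers for the 5th to 95th percentiles, n = 2 arrays per group. The median is 2.34 in kmg control, 6.17 in kmg RNAi, 2.82 in the arrays labelled kmg RNAi with aly mutant, 2.36 in dMi-2 control and 4.9 in dMi-2 RNAi.

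Against kmg control, the same arrays showed losses of late germline genes and gains of early ones. All 21 spermatid genes fell (median -6.02, camera adjusted p = 2.4e-11, adjusted p = 0.35 with an estimated correlation), as did all 13 cup and comet genes (median -7.93, camera adjusted p = 1.1e-07, adjusted p = 0.22 with an estimated correlation) and all 7 Y-linked genes (median -6.09, camera adjusted p = 6.6e-05, adjusted p = 0.22 with an estimated correlation). All 12 replication genes rose (median 2.89, camera adjusted p = 0.0075, adjusted p = 0.22 with an estimated correlation), with Orc1 at 5.79 ± 0.18 and PolA1 at 5.71 ± 0.22, and bam rose by 3.63 ± 0.26. Of 9 proteasome genes 6 fell and 1 rose (camera adjusted p = 0.016, adjusted p = 0.49 with an estimated correlation), and of 37 ribosomal protein genes 32 rose and 3 fell (camera adjusted p = 0.0075, adjusted p = 0.83 with an estimated correlation). CG31870 (-12.28 ± 0.16) and CG2127 (-12.22 ± 0.21) fell most, and CG9839 (7.27 ± 0.19) rose most. In all, 7059 genes changed (71.9%), 4850 higher and 2209 lower, with a median of 1.01 over all genes (0.74 after median centring). The 937 genes raised from background by kmg RNAi had a median of 0.25 here, with 330 higher and 8 lower. Adjusted over the list alone, 21, 13, 7, 12, 7 and 35 members of the 6 lists were called. No other list passed camera, while fry called 18 of 24. The medians of the fat body list (0.85) and the oogenesis and digestive lists (0 and 0) were not matched by their means (-0.41, -0.08 and -1.17).

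**Figure D4:**
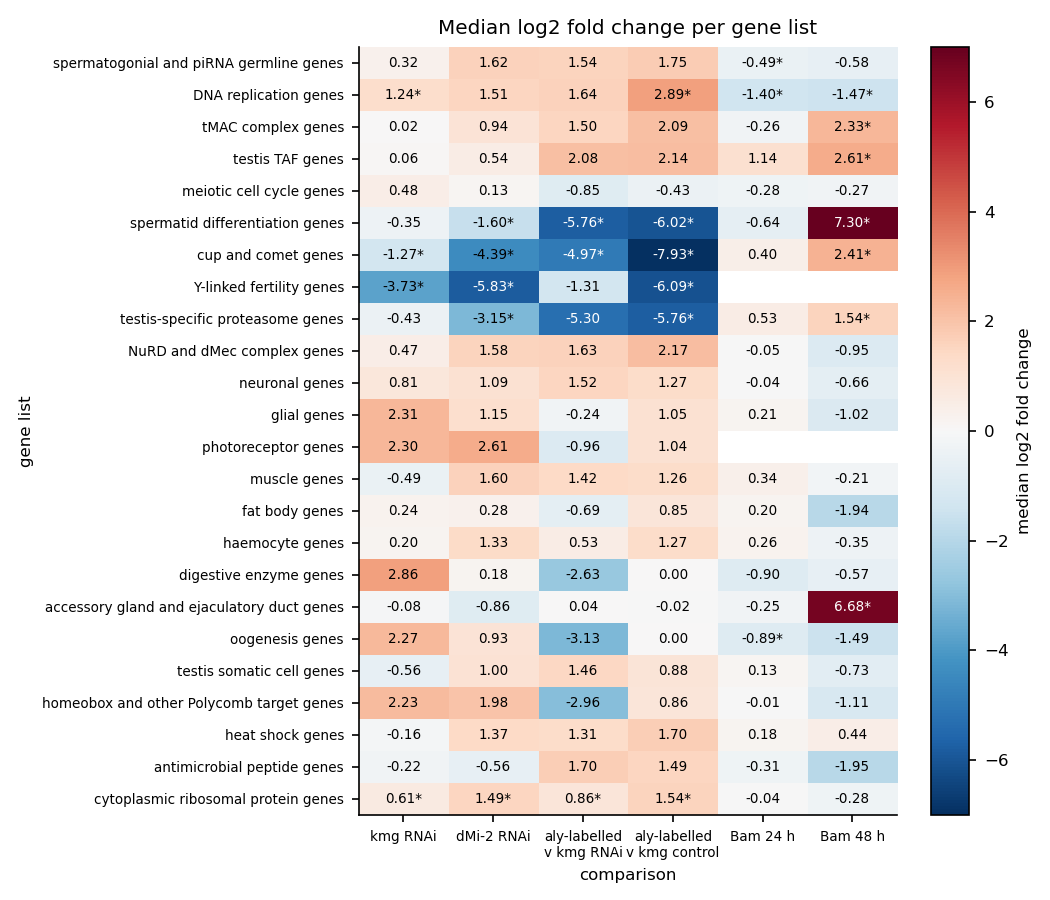
Median log2 fold change of each gene list (lines) in 6 comparisons (columns), with the colour scale from -7 to 7 and asterisks where camera with the preset correlation gave an adjusted p under 0.05. The Y-linked list has medians of -3.73 in kmg RNAi and -5.83 in dMi-2 RNAi, and the spermatid list -0.35 and -1.6.

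At 24 h after Bam induction, limma called 0 of 6626 genes (354 at an unadjusted p under 0.05, and 0 with a trended and robust prior). The bam transcript was at 10.72 and 11.79 on the hs-Bam arrays without heat shock, against 8.81 on the bam array without hs-Bam. At 24 h it was at 9.71 and 10.9 with hs-Bam and at 8.79 without, so no rise of bam was seen then. The kmg level was 2.2 before and 7.45 after (5.24 ± 0.47, adjusted p = 0.21), with 8.07 and 6.82 on the 24 h arrays, and its single-array change in bam flies without hs-Bam was -0.01. The genes with the greatest differences were chosen after their values were seen. They were fest (6.73 ± 0.49), the RNA-binding protein gene Rbp4 (6.67 ± 0.48), betaNACtes2 (6.13 ± 0.67) and Gld2 (5.32 ± 0.3, adjusted p = 0.097), with Ccdc114 at -3.69 ± 0.21, NANS at -3.34 ± 0.28, the histone gene BigH1 at -3.17 ± 0.35 and exu at -3.02 ± 0.35. In bam flies without hs-Bam, fest differed by 0, Rbp4 by 0.61, betaNACtes2 by 0, Gld2 by -0.22, Ccdc114 by -0.36, NANS by -0.05, BigH1 by -0.85 and exu by -0.36. No spermatocyte regulator list passed camera, and their members, also named after their values were seen, differed in both directions. The 7 measured tMAC genes had a median of -0.26, with topi at -2.06 ± 0.35 (adjusted p = 0.39). The 10 meiotic genes had a median of -0.28, with the cohesin-related SA2 at 4.17 ± 0.23 (adjusted p = 0.097) and CycB at -1.65 ± 0.63, bol at -1.23 ± 0.67 and twe at -0.88 ± 0.46. The 3 measured testis TAF genes had a median of 1.14 (camera adjusted p = 0.39). With a replicate block 3 genes were called, and with the replicate numbers of the 24 h arrays exchanged in it, an alternative chosen after seeing the data, 95.

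The 12 replication genes had a median of -1.4 at 24 h (camera adjusted p = 2.3e-16, adjusted p = 0.7 with an estimated correlation), with 0 called over all genes and 9 adjusted over the list alone, among them Prim1 at -2.28 ± 0.24 and PCNA at -1.34 ± 0.21. The 15 spermatogonial genes had a median of -0.49 (camera adjusted p = 9.6e-05, adjusted p = 0.7 with an estimated correlation), with zpg at -1.02 ± 0.19, and the 3 measured oogenesis genes -0.89 (camera adjusted p = 0.00037, adjusted p = 0.7 with an estimated correlation), with 0 and 1 called adjusted over the list alone. Camera called no other list and fry called 0 of 22. Mean and median differed in sign for the heat shock, testis somatic cell and Polycomb target lists, and the medians of the neuronal and Polycomb target lists (-0.04 and -0.01) changed sign under a scaling alternative. The spermatid list had 1 measured gene and the Y-linked and photoreceptor lists had 0. Of the 5 heat shock genes 0 were called, and their median change was 0.18 with hs-Bam and 0.38 on the single arrays without it. A change of at least log2 1 was seen for 118 genes on the single bam arrays and for 230 genes in hs-Bam means, of which 5 moved the same way in both. Accessory gland genes at log2 4 or more numbered 8 and 2 on the arrays without heat shock and 2 and 6 on the 24 h arrays, of 17.

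The 48 h group was a single array, which also carried accessory gland transcripts (list median log2 10.62), so its p values rest on the spread of the other hs-Bam groups and do not cover variation between 48 h samples. No array without hs-Bam was taken at 48 h, so effects of the heat shock itself were not separated from those of Bam. Against the arrays without heat shock, 118 of 7097 genes were called, 107 higher and 11 lower. The largest rises were those of fest (12.26 ± 0.66, adjusted p = 0.019), the spermatid gene ocn (10.05 ± 0.67), the phosphatase gene Pp1-13C (9.62 ± 0.73), CG43052, wuc, betaNACtes2, Rbp4 (8.53 ± 0.64), CG9692, CR17567 and CG10993. kmg rose by 7.06 ± 0.62 (adjusted p = 0.033), from 3.02 to 10.08. The falls were led by hdm, a meiotic recombination gene (-3.46 ± 0.35), with CG30016 (-3.46 ± 0.33), CG4860 (-2.93 ± 0.33) and the chromatin assembly gene asf1 (-2.46 ± 0.27) among the others. Of 9 tMAC genes 4 rose, wuc (8.98 ± 0.95), comr (7.08 ± 0.67), vis (4.19 ± 0.29) and topi (3.4 ± 0.31), with camera adjusted p = 0.00013 and adjusted p = 0.41 with an estimated correlation. Of 4 measured spermatid genes 3 rose (camera adjusted p = 0.0029), ocn, Mst87F (7.4 ± 0.45) and Mst84Dc (7.2 ± 0.33), as did 2 of 3 cup and comet genes (camera adjusted p = 0.00097) and 1 of 3 proteasome genes, Prosbeta2R2 (camera adjusted p = 0.0044). For each of these and for the 3 testis TAF genes (0 called, median 2.61, camera adjusted p = 0.0034), the adjusted p was 0.41 with an estimated correlation. The 12 replication genes had a median of -1.47 with 0 called (camera adjusted p = 0.0029, adjusted p = 0.51 with an estimated correlation). Adjusted over the list alone, 5 tMAC, 4 spermatid, 3 cup and comet, 2 proteasome, 3 TAF and 5 replication genes were called. Of 11 accessory gland genes 1 rose, SP (7.19 ± 0.68), with a list median of 6.68 (camera adjusted p = 2.4e-06, adjusted p = 0.51 with an estimated correlation) and 10 called adjusted over the list alone. Of the 10 meiotic genes SA2 rose (3.87 ± 0.35), and the lists not named here had 0 called members. By fry, the tMAC, spermatid, cup and comet, proteasome, NuRD and testis somatic cell lists were called, the last 2 downward.

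The filter needed 2 bright arrays and so removed genes seen only on the 48 h array. With 1 bright array enough, an alternative chosen after seeing the data, 1531 of 8095 genes were called (1158 higher and 373 lower), including all 118. As that filter admits genes for being bright on the 48 h array, lists were also counted without a filter, likewise chosen after seeing the data. Of 22 spermatid genes 17 were then higher and 0 lower (median 7.42), as were 7 of 13 cup and comet genes, 3 of 9 proteasome genes and 2 of 5 testis TAF genes, while only 2 of 9 tMAC genes were. Without replicate 1 of the arrays without heat shock, which carried accessory gland transcripts (median log2 5.74 in this set), 61 genes were called, and 80 without replicate 2. All 61 and all 80 were higher, so that no fall held without either array, and topi, SA2, CG43052 and both called cup and comet genes, soti and m-cup, were lost without either, and ocn, wuc and SP without replicate 1. Quantile normalization gave 899, of which 567 were lower.

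**Figure D5:**
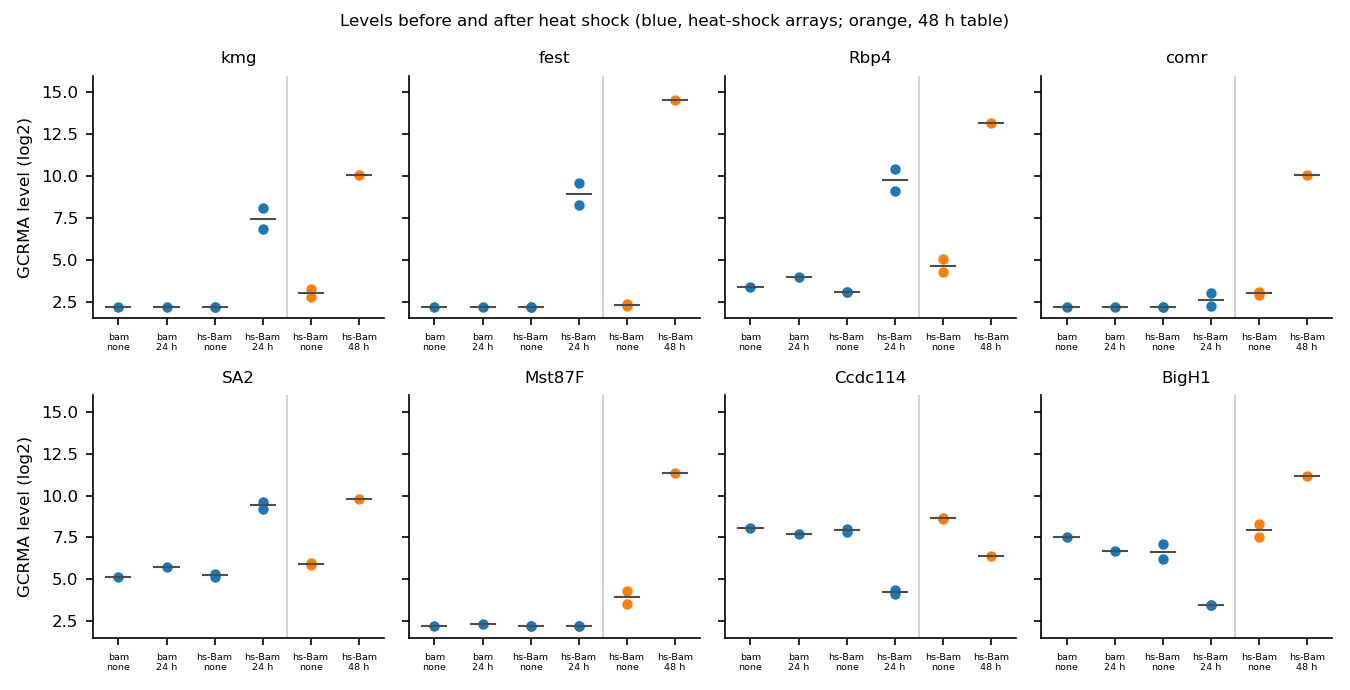
Levels (GCRMA, log2) of 8 genes, chosen after their values were seen, on the 6 heat-shock arrays (blue) and on 3 arrays of the separately normalized 48 h table (orange), with points for arrays and lines for means. The level of kmg is 2.2 before and 7.45 at 24 h in the first set, and 3.02 before and 10.08 at 48 h in the second.

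Genes raised by the knockdowns were compared with the Bam time course to ask whether they belong to normal early differentiation. Of the 2520 genes raised by kmg RNAi, 1439 were measured at 24 h, with a median change of 0.04 (limma fry adjusted p = 0.97), and 1562 at 48 h, with a median of -0.36 (limma fry adjusted p = 0.094), 9 higher and 5 lower. The latter median was -0.04 without a filter and -0.58 with a log2 fold minimum of 2, both past the unadjusted threshold of fry, so that the outcome at 48 h depended on these choices. Of the 937 raised from background, 87.7% were not measured at 24 h and 82.4% not at 48 h, as too few arrays reached log2 4. The 165 measured at 48 h had a median of -1.02 (limma fry adjusted p = 0.034), and 329 of the 1004 that dMi-2 RNAi raised from background had -1.17 (limma fry adjusted p = 0.036). The filter dropped genes bright on the 48 h array alone and so favoured lower medians. The genes raised by dMi-2 RNAi had medians of 0.05 at 24 h (limma fry adjusted p = 0.11, and past the unadjusted threshold with a median of 0 without a filter) and -0.42 at 48 h (limma fry adjusted p = 0.0043), where the median of all genes was -0.31. At 48 h 20 of them were higher and 4 lower of 3665 measured. Without replicate 1 of the hs-Bam arrays without heat shock, the median was -0.4 and the unadjusted p of fry was above 0.05.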

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

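All tests in this part were chosen after the results were seen, except the difference between the knockdown effects, and their limits were set with the values known, except for the seminal fluid genes outside the list. The effects of kmg RNAi and dMi-2 RNAi differed for 5680 genes by the test of the difference itself. The kmg transcript differed by -6.08 between the effects. List medians of the difference were 1.39 for spermatid, 3.1 for cup and comet, 2.77 for testis proteasome and -0.82 for ribosomal protein genes. No group held more than 2 arrays, so no array was tested against its own group.

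Accessory gland transcripts were high on the replicate 1 arrays of both dMi-2 groups and on the 48 h array (list median 10.62). In the dMi-2 groups, 12 of 16 genes lay at least 3 log2 units above replicate 2 in both. An effect of dMi-2 RNAi is argued against by the controls, whose arrays differed by a median of 9.05, and expression by the germ cells of the 48 h array by kmg control testes, whose higher median was 2.82 in their own normalization. Attached tissue was tested on 8 seminal fluid genes outside the list, whose median differences were 4.53 in dMi-2 control, 2.63 in dMi-2 RNAi and 3.5 at 48 h. As the limit of 3 in each, set before these values were seen, was missed in dMi-2 RNAi, attached tissue may account for the transcripts but stays open, and the labels state that accessory glands were removed from the knockdown testes.

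The kmg level in the arrays labelled kmg RNAi with aly mutant was near that of kmg control. An exchange with the control arrays is argued against by the spermatid list, which was lower by a median of -6.02 with all 21 genes called. A larger share of spermatocytes alone was tested on 13 other tMAC and testis TAF genes. Their median rise was 1.86 (SD 1.42) against 3.81 for kmg, with 1 gene at or above kmg. As their changes ran from -0.99 to 3.85, with nht, can and comr near kmg, the median does not decide, and this explanation stays open. Weaker knockdown without UAS-dicer2 may account for the level but cannot be told apart from an effect of the aly alleles, since both come with the same arrays. Dcr-2 rose by 1.1 there, a call lost without replicate 2 of these arrays, and its probe set reads the endogenous gene as well.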

How the results depend on the processing

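Tests chosen only after the results were seen were the 1-array filter, the exchanged replicate block, the fits without the 2 dMi-2 arrays with accessory gland transcripts, the aly comparison in the 48 h table, the list counts without a filter and of accessory gland genes in fits of single comparisons, and the genes chosen on 1 kmg control array. Of the alternatives, 109 gene counts stayed within 1.5 times the reported one and 15 did not, and of the medians of raised genes 109 kept their direction and side of the threshold, 5 passed it and 1 lost it. No median of raised genes changed sign. Among the called genes the majority turned from higher to lower for kmg RNAi after quantile normalization and median centring, and at 48 h after quantile normalization. Requiring a log2 fold change of at least 2 gave 2380 genes for kmg RNAi, 3711 for dMi-2 RNAi, 4735 and 4459 for the arrays labelled aly mutant against kmg RNAi and kmg control, 3189 for the difference and 902 raised by both, as a stricter minimum must lower counts. The median of kmg-raised genes at 48 h was then -0.58 and passed the unadjusted threshold of fry. Without a filter, 1214 genes were called at 48 h, and the kmg-raised genes had -0.04 there and the dMi-2-raised genes 0 at 24 h, both past that threshold. At 48 h the count was 30 with the log2 6 filter, 899 with quantile normalization, 2121 with all arrays of the table in 1 fit and 1531 with the 1-array filter. At 24 h it was 3 with a replicate block, 42 with all arrays of the 48 h table in 1 fit and 95 with the exchanged replicate block. Apart from the fold minimum and the filters, the cause was not tested.

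Leaving out 1 array gave 61 to 80 genes at 48 h, 0 at 24 h, 4346 to 4475 for kmg RNAi, 6263 to 6607 for dMi-2 RNAi, 6803 to 6967 and 6654 to 6979 for the aly comparisons, 5203 to 5808 for the difference and 1809 to 1952 raised by both. Group means of 1 array were assumed to vary like the other groups. Medians of dMi-2-raised genes ran from 0.03 to 0.05 at 24 h and from -0.45 to -0.38 at 48 h, 0.65 to 0.88 under kmg RNAi and 1.19 to 1.41 in the aly comparison, and those of kmg-raised genes from -0.94 to -0.57 there. At 24 h, the dMi-2-raised genes passed the threshold without dMi-2 control replicate 2 or without dMi-2 RNAi replicate 2, and at 48 h they lost it (-0.4) without replicate 1 of the arrays without heat shock. Of 32 list calls made with camera, 0 held with an estimated correlation and 26 with fry. The log2 floor hides changes of genes near it. Not run were the value table in place of the knockdown table, whose values are identical, the value table for the 48 h array, which would mix normalizations, and a replicate block for 48 h, whose group held 1 array.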

Other observations

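The tests of explanations in this part were chosen after the results were seen. The lowered genes of dMi-2 RNAi overlapped those of the arrays labelled aly mutant. Of 2122 genes lowered by dMi-2 RNAi 1559 were lower in the latter against kmg RNAi, with 629.7 for independent lists (odds ratio 13), and the comparisons share no array. Among them were Prosalpha3T, Pp1-Y2, Prtl99C, S-Lap5 and RpL10Aa. Across genes the fold changes correlated at r = 0.53 (Spearman 0.375). Of 4446 genes raised by dMi-2 RNAi 2505 were also higher there, with 1909.4 for independent lists, among them chp and unc-13.

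In the heat-shock arrays, replicate deviations from the group mean correlated across genes at -0.734 between the arrays without heat shock and the 24 h arrays. Between the dMi-2 groups, whose replicate 1 arrays carried accessory gland transcripts, the correlation was 0.619. Between the other pairs of knockdown groups it lay between -0.104 and 0.217. The histone gene BigH1, chosen after its values were seen, was at 3.49 and 3.47 on the 24 h arrays, against 7.09 and 6.22 before, and went from 7.52 to 6.67 on the single bam arrays without hs-Bam. At 48 h, in the other normalization, it was at 11.18, above the 8.32 and 7.53 before.

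A hypothesis was that genes raised by kmg RNAi need aly. The choice of genes for high values on shared arrays was tested by choosing and testing on different kmg RNAi arrays, with a median of -0.89. The filter, however, had used both arrays. Genes that passed it only through them were thus also chosen on the testing array. As the median covers these genes too, it does not settle the question. Loss of aly and the higher kmg level of these arrays cannot be told apart, because no array had the aly mutation with a low kmg level. The genes raised from background returned to a median of 0.25 from kmg control, as either may give, and the genes lowered by kmg RNAi stayed at -1.42, with 507 higher and 1141 lower of 2159. As the kmg control arrays served in both choosing and testing, genes were also chosen on 1 control array and compared with the other. The medians were then 0.26 and 0.25 for genes raised from background and -1.26 and -1.17 for lowered genes, chosen by the fold minimum alone.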
